A study of Mus musculus with 15 samples.

How the data were processed

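The series holds 15 RNA-seq libraries of ventricular cardiomyocytes, the contractile muscle cells of the heart, isolated from wild-type C57BL/6 mice. Per the labels, 4 libraries come from postnatal day 1 (P1), 4 from postnatal day 3 (P3) and 7 from adults aged 8 to 12 weeks. Total RNA was extracted with TRIzol and libraries were made with an Illumina TruSeq kit, per the labels' protocols. Groups and replicate numbers were taken from the library titles. The labels do not say whether the libraries of a group came from separate animals, litters or pools of hearts, so the p-values measure only the spread between these libraries, which may in part be technical.

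The deposited table gives RPKM, reads per kilobase of gene per M reads (M for mega), which the authors computed for 9666 rows named by gene symbol. HISAT2, Partek 6.6 and the genome build mm10 are named per the submitters' processing notes, without role or order. The gene annotation, the counting rule, the handling of strand and of reads shared between similar genes, and the filter that chose the rows are not given in the sources used here. Every deposited value lies above 0.1 RPKM, the lowest being 0.100 RPKM. A gene near 0 in any library therefore has no row, which removes many genes that are silent in adult cardiomyocytes. Of the rows, 15 carry names altered to dates by a spreadsheet; these were tested but are not named.

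Because the authors counted whole reads, the RPKM values of a gene are whole multiples of the worth of 1 read, and this was used to recover the depth. The commonest ratio of values in each pair of libraries gave the starting relative depths, which 72 of 105 pairs matched. With the depths refined on the recovered rows, 8027 rows (83.0%) gave whole reads in all 15 libraries within a relative tolerance of 1e-05. After the values were jittered by 1%, 0 rows did so. Rows with very many reads in any library cannot be resolved at this tolerance and were not recovered. The absolute scale was set by the depth most often found among genes with 1 transcript in the GENCODE annotation of mm10, which 89 of 583 such genes gave. The read total that divides each library's values was 12.6 to 22.2 M in adults, 10.5 to 11.3 M at P1 and 9.47 to 13.6 M at P3. At these totals, 1 RPKM in a gene of 2 kb rests on 18.9 to 44.3 reads. Replicates were compared by a chi-square test of the recovered reads. The closest pair in any group had a chi-square of 4.75 per degree of freedom, above the 1 that counting noise alone gives, and no pair was treated as a single library. This cannot tell whether 2 libraries were made from the same RNA.

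Values were tested as log2(RPKM + 1), so a log2 change here is on that scale and understates the change of genes near 1 RPKM. Rows with at least 1 RPKM in at least 4 libraries were kept, 9389 in all. A linear model with 3 group means was fitted to all 15 libraries with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend). Contrasts were neonatal (the mean of the P1 and P3 means) minus adult, P1 minus adult, P3 minus adult and P3 minus P1. A gene was called, and is said to have risen or fallen, at a Benjamini-Hochberg adjusted p under 0.05 together with an absolute log2 change of at least 1. Adjusted p-values of single genes are from limma and two-sided. Cdh2 and Ctnnb1 were also tested by exact two-sided permutation of the libraries. As a further reading of every change, the libraries were scaled by median-of-ratios factors, which set the typical gene to equal levels.

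Gene lists were fixed before the data were examined: 33 pathways, gene families, a dissociation stress list and markers of cardiomyocytes and of other cell types. Of these, 25 had at least 5 tested members and were tested with limma's camera, which compares the members of a list with all other genes, at a preset correlation of 0.01 with Benjamini-Hochberg adjustment over the lists. The test was repeated with the correlation estimated from the data, and with fry, both on the deposited values only. Another 5 lists had fewer tested members, and those of 4 are given as counts. The mitochondrially encoded genes (0 of 15 members), macrophage and leukocyte markers (0 of 24) and epicardial and mesothelial markers (0 of 15) had no row and were not analysed here. Other lists were cut in part. Rows were found for 10 of 37 beta-catenin/TCF targets, 35 of 68 Wnt genes, 21 of 38 DNA replication genes and 9 of 20 fibroblast markers. Library scores are means of log2(RPKM + 1) over the members of a list. The named genes were chosen by a rule fixed before the data were examined: Cdh2 and Ctnnb1; the 4 largest rises and 4 largest falls among called genes whose libraries do not overlap between the groups and whose higher group mean is at least 10 RPKM; and for each list the called member or, for lists past the threshold, the 2 called members with the largest change and a higher group mean of at least 2 RPKM. Some genes that the rule chose, and results that rest on them alone, are not reported here and were not replaced. Any other gene that is named was chosen after its values were seen. Coordinates are GENCODE positions on mm10, counted from 1, matched by symbol for 9483 rows.

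The same steps were tested on simulated data in which genes above a minimum mean level were changed by known amounts. The noise was normal, independent between genes and of equal spread in all groups. No shift of the whole table, outlying library or correlation between genes was simulated, so the numbers hold for those settings and not for the real libraries. Of 100 genes changed by 1.5 on the log2 scale, 97 were recovered for neonatal against adult, 96 for P1 against adult, 93 for P3 against adult and 92 for P3 against P1. Of 100 genes changed by 3, the numbers were 99, 98, 100 and 99. Among the unchanged genes, 0 of 9068, 0 of 9083, 6 of 9077 and 5 of 9078 were called, in the same order. Alternatives fixed before the data were examined covered the pseudocount, the filter, 4 rescalings, the limma options, the libraries in the fit, a block by replicate number, each library left out in turn and no fold minimum. Further alternatives, chosen after seeing the data, were voom on the recovered reads and a fit without the 4 libraries lowest in cardiomyocyte markers. Tables were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.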

Results

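RNA of isolated ventricular cardiomyocytes was sequenced at P1, at P3 and in adults, which spans the days when the mouse heart can still renew its muscle and the adult stage when it largely cannot. The series was made to look for mediators of cardiac muscle regeneration, and its title names N-cadherin (Cdh2) and beta-catenin. Read totals behind the RPKM values averaged 17.9 ± 3.03 M in adults (SD, n = 7), 10.9 ± 0.413 M at P1 (n = 4) and 11.3 ± 1.85 M at P3 (n = 4). The 9666 rows held about 26.2% ± 5.28 of that total in adults, 50.4% ± 1.08 at P1 and 51.4% ± 3.09 at P3. These shares are estimates. For rows without recovered reads they rest on the RPKM and the median length of the gene's GENCODE transcripts, and 29 rows without a length were left out. The 20 highest rows of a library took 25.6% ± 0.818 of its RPKM sum in adults, 10.6% ± 1.14 at P1 and 9.25% ± 0.526 at P3. The median row stood at 2.86 ± 0.618 RPKM in adults, 8.59 ± 0.161 at P1 and 9.20 ± 0.309 at P3. Adult libraries fell into 2 sets, with medians of 2.02 to 2.68 RPKM in replicates 1, 2 and 3 and 3.15 to 3.52 in replicates 4, 5, 6 and 7. The cause of that split was not tested. Because the median differed between groups, counts and list medians are given for the deposited RPKM and again after median-of-ratios scaling. For named genes, a call that scaling removed is stated. Scaling moved the median log2 change of all genes from 1.25 to 0.02 for neonatal against adult libraries and from 0.08 to 0.00 for P3 against P1.

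Markers of cell types differed between and within the groups, as the plot of marker scores per library shows. The score of 18 pan-cardiomyocyte markers, among them Tnnt2 (cardiac troponin T) and Actn2 (alpha-actinin of the Z disc), lay between 7.80 and 8.53 in the 7 adult libraries. At P1 it lay between 7.23 and 7.39 in replicates 2, 3 and 4 and at 6.03 in replicate 1. At P3 it was 6.42 in replicate 1 and 4.69, 4.02 and 3.98 in replicates 2, 3 and 4. The score of 13 endothelial markers, such as Pecam1 and Cdh5 of the vessel lining, ran the other way, with 0.56 to 4.66 in adults, 4.20 to 5.20 at P1 and 5.82 to 7.13 at P3. Adult libraries thus also differed in endothelial RNA, from 0.56 in replicate 7 to 4.66 in replicate 4. The score of 9 fibroblast markers was 5.31 in P1 replicate 1 against 2.86 to 3.17 in the other P1 libraries, 3.56 to 4.10 at P3 and 1.05 to 3.62 in adults. Smooth muscle and pericyte markers (5 members) scored 2.62 ± 0.622 in adults, 3.34 ± 0.399 at P1 and 4.15 ± 0.459 at P3.

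**Figure D1:**
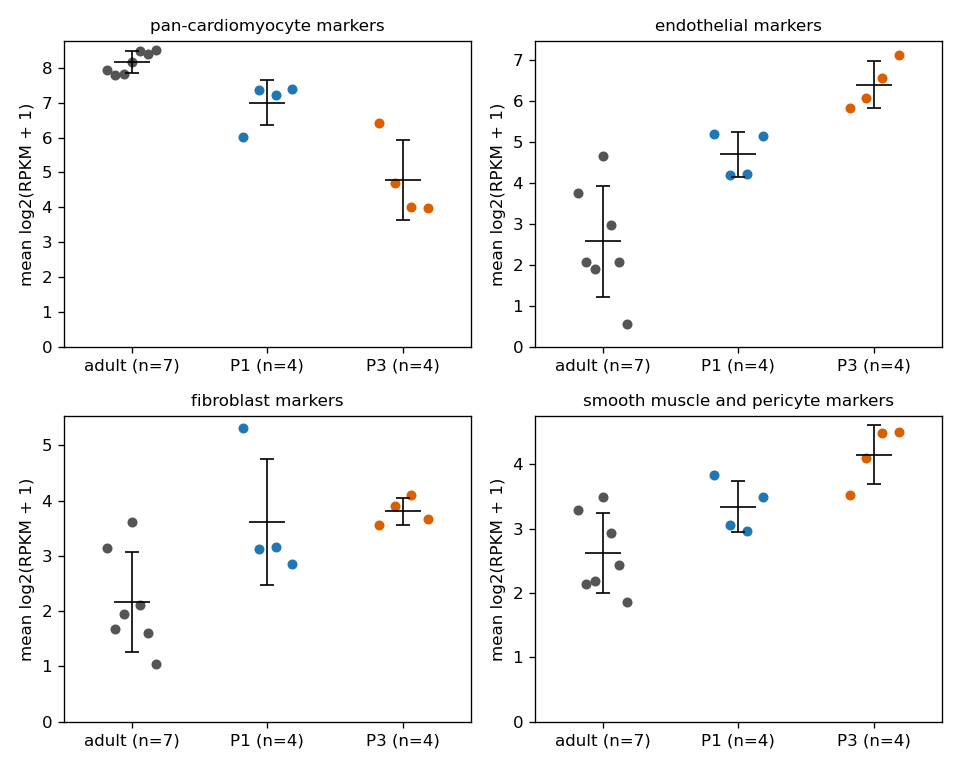
Mean log2(RPKM + 1) of the cardiomyocyte, endothelial, fibroblast and smooth muscle marker lists in each library; points are libraries, and the horizontal mark and bars give the mean and SD of the adult (n = 7), P1 (n = 4) and P3 (n = 4) groups. P3 replicates 2, 3 and 4 sit between 3.98 and 4.69 for cardiomyocyte markers, below every other library, and all P3 libraries sit above 5.81 for endothelial markers.

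N-cadherin and beta-catenin RNA were both higher in neonatal than in adult libraries as deposited, and after scaling this held for beta-catenin alone. Cdh2, which encodes the adhesion receptor of the intercalated disc (chromosome 18, 16588877 to 16809246, minus strand), stood at 24.4 ± 5.20 RPKM in adults (SD, n = 7), 84.0 ± 23.2 at P1 (n = 4) and 51.6 ± 17.9 at P3 (n = 4). Its neonatal minus adult log2 change was 1.37 ± 0.20 (SE, limma adjusted p = 3.29e-06; exact permutation p = 0.000311), and every neonatal library lay above every adult one. After scaling the change was -0.21 (exact permutation p = 0.392). Ctnnb1, which encodes beta-catenin, the partner of cadherins at the junction and a transcriptional coactivator of Wnt signalling (chromosome 9, 120929216 to 120960507, plus strand), stood at 50.1 ± 11.2 RPKM in adults, 202 ± 23.1 at P1 and 309.6 ± 37.9 at P3. It rose by 2.32 ± 0.17 (limma adjusted p = 4.19e-10; exact permutation p = 0.000155, the smallest that 6435 arrangements can give). After scaling its change was 0.72 (exact permutation p = 0.000622), under the fold minimum but above 0 in the exact test. The upper quartile of the changes of all genes was then 0.695, so Ctnnb1 did not stand out by size.

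The age groups taken singly gave the same picture for Ctnnb1 and a split one for Cdh2. Against adults, Ctnnb1 rose by 2.02 at P1 and 2.63 at P3, and after scaling the changes were 0.46 and 0.98 (exact permutation p = 0.00303 for each of the 4 values, the smallest that 330 arrangements can give). Cdh2 rose by 1.72 at P1 and 1.02 at P3 against adults (exact permutation p = 0.00303 for each), whereas after scaling it differed by 0.18 at P1 (exact p = 0.382) and by -0.61 at P3 (exact p = 0.00606). Between P3 and P1, neither gene was called. Cdh2 differed by -0.70 ± 0.27 (SE, limma adjusted p = 0.0922; exact permutation p = 0.0571) and Ctnnb1 by 0.61 ± 0.24 (limma adjusted p = 0.0939; exact permutation p = 0.0286, the smallest that 70 arrangements can give). After scaling these differences were -0.79 and 0.52. Among the neonatal libraries, Cdh2 was lowest in P3 replicate 4 (33.8 RPKM; cardiomyocyte marker score 3.98) and highest in P1 replicate 2 (106 RPKM; score 7.38). Ctnnb1 was the reverse, highest in P3 replicate 4 (359 RPKM, endothelial score 7.13) and lowest in P1 replicate 2 (176 RPKM, endothelial score 4.20). Without the 4 libraries lowest in cardiomyocyte markers (an alternative chosen after seeing the data), its neonatal change was 2.19. Those that remain were still below adults in cardiomyocyte markers.

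**Figure D2:**
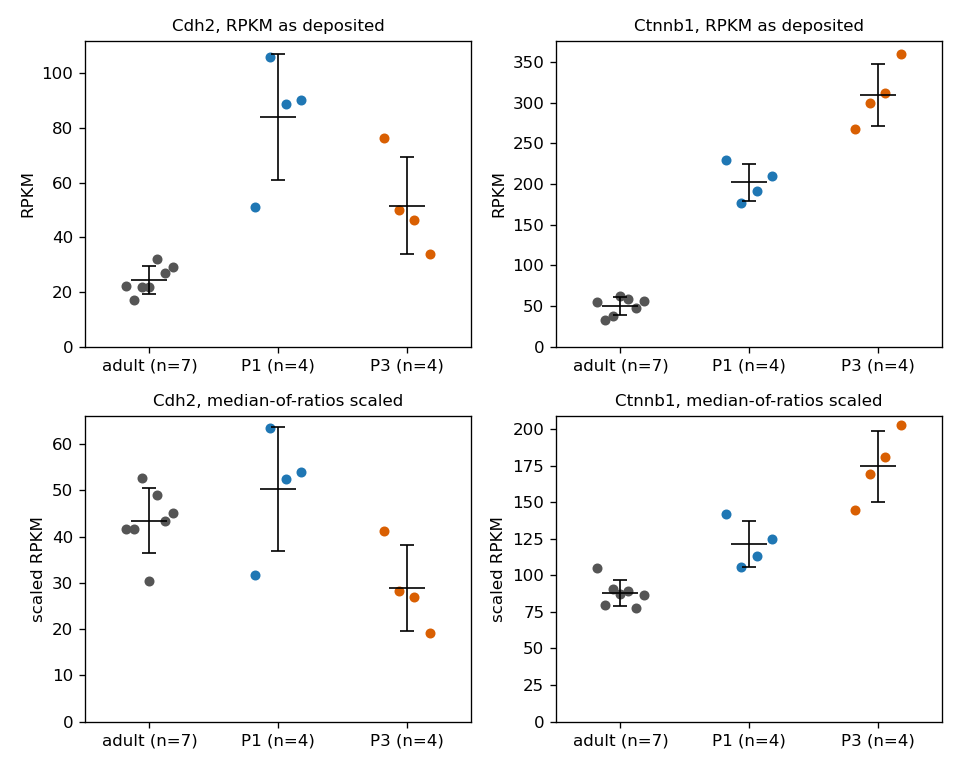
Cdh2 (left) and Ctnnb1 (right) in each library, as deposited RPKM (top) and after median-of-ratios scaling (bottom); points are libraries, and the horizontal mark and bars give the mean and SD of the adult (n = 7), P1 (n = 4) and P3 (n = 4) groups. As deposited, every neonatal library lies above the adult ones for both genes (adult highest 32.2 for Cdh2 and 62.4 for Ctnnb1); after scaling, the Cdh2 means are 43.4 in adults, 50.4 at P1 and 28.9 at P3.

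Among the genes with the largest differences between neonatal and adult libraries, Ctgf, H19, Vim and Tagln were higher and Ckmt2, Hrc and Rpl3l lower in neonatal ones. Ctgf, a secreted matricellular protein and target of the Hippo-YAP pathway, averaged 5.95 ± 3.72 RPKM in adults (SD, n = 7), 1015 ± 249 at P1 and 1656 ± 774 at P3 (n = 4 each), a rise of 7.59 ± 0.31 (SE, limma adjusted p = 4.87e-13). The imprinted non-coding RNA H19 (chromosome 7, 142575529 to 142578143) rose by 7.07 ± 0.47, from 0.406 ± 0.236 RPKM to 169.9 ± 146 at P1 and 443 ± 432 at P3. Vim, which encodes the intermediate filament vimentin of mesenchymal and endothelial cells (chromosome 2, 13573927 to 13582826), rose by 6.72 ± 0.54, and Tagln, which encodes the smooth muscle actin-binding protein transgelin (chromosome 9, 45929619 to 45936058), by 6.71 ± 0.28. In the other direction, Ckmt2, the mitochondrial creatine kinase of the sarcomere (chromosome 13, 91853387 to 91876885), changed by -6.33 ± 0.36 (limma adjusted p = 1.22e-11), from 997 ± 228 RPKM in adults to 18.6 ± 6.58 at P1 and 11.0 ± 13.9 at P3.

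Hrc, a calcium-binding protein of the sarcoplasmic reticulum (chromosome 7, 45335290 to 45338974), changed by -5.79 ± 0.26 (SE, limma adjusted p = 1.52e-12). Rpl3l, a striated-muscle form of a ribosomal protein (chromosome 17, 24727820 to 24736143), changed by -5.62 ± 0.19. How reads shared by Rpl3l and the broadly expressed Rpl3 were counted is not given in the sources used here. All of these 7 genes kept their direction and call after scaling, with Ctgf at 6.08 and Ckmt2 at -7.84. In all, 6071 of 9389 genes were called as deposited, 5496 higher and 575 lower in neonatal libraries, so that 90.5% of the calls were higher. After scaling, 3471 were called, 1484 higher and 1987 lower (42.8% higher), and all of the 1484 and 575 were called in the same direction by both. The direction of a gene whose change is small beside the median shift of 1.25 thus depends on the scaling.

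Contractile and metabolic genes of the adult heart were lower in neonatal libraries. Of 26 adult sarcomere genes, 21 fell and 0 rose (median log2 change -1.78, after scaling -3.35, camera adjusted p = 1.62e-22). Tcap (telethonin, a Z-disc protein that caps titin) changed by -4.96 and Myoz2 (a calsarcin of the Z disc) by -3.41. Of 43 fatty acid oxidation genes, 32 fell and 3 rose (median -1.71, scaled -3.29, camera adjusted p = 2.11e-28). The lipid droplet protein Plin5 changed by -4.37 and the triglyceride synthase Dgat2 by -3.84. Of 65 genes of oxidative phosphorylation and the TCA cycle, 45 fell and 2 rose (median -1.26, scaled -2.87, camera adjusted p = 1.09e-36). Besides Ckmt2, Cox7a1, a muscle form of a cytochrome c oxidase subunit, changed by -4.40. Of 32 calcium handling and ion channel genes, 12 fell and 3 rose (median -0.78, scaled -1.99, camera adjusted p = 1.93e-15), among them Pln (phospholamban, the inhibitor of the calcium pump) at -3.85. The 18 pan-cardiomyocyte markers, 15 of which are also members of another list, behaved alike, with 15 fallen and 0 risen (median -2.25, scaled -3.74, camera adjusted p = 1.16e-17). The oxygen carrier Mb changed by -4.89 and Cmya5 by -4.05. With an estimated correlation none of these 5 calls held. The adjusted p was 0.163 with an estimated correlation for the sarcomere, fatty acid, calcium and cardiomyocyte lists, and the adjusted p was 0.230 with an estimated correlation for the oxidative list. The cardiomyocyte marker score was also lower in the neonatal groups, at 7.01 ± 0.657 at P1 and 4.78 ± 1.14 at P3 against 8.17 ± 0.311 in adults. Without the 4 neonatal libraries lowest in these markers (P1 replicate 1 and P3 replicates 2, 3 and 4, an alternative chosen after seeing the data), 12 sarcomere, 21 fatty acid, 11 oxidative, 9 calcium and 10 cardiomyocyte marker genes fell, with medians of -0.94, -1.01, -0.57, -0.58 and -1.22, while 0, 3, 2, 5 and 1 rose. After scaling all libraries, 26 sarcomere, 37 fatty acid, 62 oxidative, 23 calcium and 17 cardiomyocyte marker genes fell and 0 rose.

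Genes of DNA replication and of the Hippo-YAP pathway, which links cell contacts to growth, were higher in neonatal libraries. Of 21 DNA replication genes, 17 rose and 0 fell (median 1.89, scaled 0.82, camera adjusted p = 0.0485, and adjusted p = 0.842 with an estimated correlation). Mcm3 and Mcm6, subunits of the replicative helicase, rose by 3.68 and 3.46. Of 16 Hippo-YAP/TEAD target genes, 14 rose and 0 fell (median 2.66, scaled 1.36, camera adjusted p = 0.0249, and adjusted p = 0.788 with an estimated correlation). Ctgf led, and Cyr61, another secreted matricellular protein, rose by 4.37. The DNA replication call was lost when any of adult replicates 1, 3, 4, 5, 6 or 7 or P3 replicates 1, 2 or 4 was left out, with adjusted p between 0.0501 and 0.0846, and the Hippo-YAP call without adult replicate 4 (adjusted p = 0.0514). The former was also lost with a block by replicate number (0.146), without the limma trend (0.0583) and with a 5 RPKM filter (0.0636), and the latter with that filter (0.0581). Of 13 cyclins, CDKs and E2F factors, 12 rose and 1 fell (median 1.73, scaled 0.71, camera adjusted p = 0.241, after scaling 0.0239, and adjusted p = 0.842 as deposited with an estimated correlation). The growth regulator Myc rose by 4.90, while Tfdp2, a dimer partner of E2F, was the gene that fell. Of 21 cell cycle inhibitors, 12 rose and 0 fell (median 1.48, scaled 0.20, camera adjusted p = 0.706), with Cdkn1a (p21, an inhibitor of cyclin-dependent kinases) at 4.71. Only 4 of 42 mitosis and cytokinesis genes had rows: the spindle checkpoint gene Mad2l1 and the cytokinesis motor Kif20a rose by 1.59 and 1.19, whereas Cenpa stood at 0.00 and Pttg1 at -0.69. After scaling neither rise was past the fold minimum, Mad2l1 being at 0.59 and Kif20a at 0.58. Cenpa and Pttg1 were then called lower. Of 3 replication-dependent histones tested, 0 changed as deposited and 1 fell after scaling (median 0.59, scaled -0.58). After scaling, 10 DNA replication genes rose and 1 fell, 8 Hippo-YAP targets rose, 4 cyclins, CDKs and E2F factors rose and 1 fell, and 5 inhibitors rose and 3 fell. No value here separates these rises from RNA of other cell types or from the isolation of the cells, as all 13 endothelial markers and 22 of 29 immediate early and dissociation stress genes rose too. Among P1 libraries the DNA replication score was highest in replicate 1, at 3.68 (others 2.61 to 2.86), where the fibroblast score was 5.31. Rn45s, the ribosomal RNA precursor, stood at 83.7 ± 40.2 RPKM in adults, 499 ± 438 at P1 and 478 ± 485 at P3.

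Adherens junction and Wnt lists were not past the threshold in neonatal libraries, while the intercalated disc list was, in the other direction. Of 20 genes of the adherens junction and the cadherin-catenin complex, 14 rose and 1 fell (median 1.80, scaled 0.51, camera adjusted p = 0.279). Iqgap1, a scaffold that binds cadherin and beta-catenin, rose by 4.28, and the heart-enriched alpha-T-catenin gene Ctnna3 was the one that fell, by 1.23 on the log2 scale. Of 4 other cadherins tested, 3 rose (median 2.33, scaled 0.87): Fat1, an atypical cadherin, by 4.00, the endothelial cadherin Cdh5 by 3.52 and the protocadherin Pcdh7 by 1.15, a call that scaling removed (-0.29). Of 31 Wnt ligands, receptors and pathway components, 23 rose and 2 fell (median 1.65, scaled 0.55, camera adjusted p = 0.265), with the Wnt carrier Wls at 2.91. Of 10 beta-catenin/TCF target genes, 6 rose and 0 fell (median 1.68, scaled 0.32, camera adjusted p = 0.279), with Myc leading this list as well. The other genes of the 37 in that list had no row, so the test does not cover them. Of 22 genes of desmosomes, gap junctions and the intercalated disc, 8 rose and 5 fell (camera adjusted p = 0.00150, and adjusted p = 0.788 with an estimated correlation). Its test pointed down although its median of 0.12 and mean of 0.32 were above 0, because camera sets a list against the other genes. After scaling the median was -1.13 and the adjusted p 0.0598, with 3 risen and 11 fallen. The adjusted p was 0.0794 after quantile normalization and 0.0649 without the 4 libraries lowest in cardiomyocyte markers, and fry pointed up (adjusted p = 0.0248). Ilk, an integrin-linked kinase, rose by 2.82, while Xirp2 and the desmosomal gene Dsp fell, with changes of -2.10 and -1.68. After scaling, 7 adherens junction genes rose and 1 fell, 6 Wnt genes rose and 2 fell, and 4 beta-catenin/TCF targets rose and 1 fell.

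Further lists mixed rises and falls. Of 28 glycolysis and lactate genes, 12 rose and 8 fell. The test pointed down (camera adjusted p = 0.00224, and adjusted p = 0.788 with an estimated correlation) although the median of 0.50 and the mean of 0.43 were above 0, and the scaled median was -1.06, with 5 risen and 16 fallen. After quantile normalization the adjusted p was 0.362. Eno1, the broadly expressed enolase, rose by 4.06 and the glucose transporter Slc2a1 by 3.89. Of 30 antioxidant genes, 13 rose and 3 fell, again with a test pointing down (camera adjusted p = 0.0269, and adjusted p = 0.842 with an estimated correlation) against a median of 0.72 and a mean of 0.98. The scaled median was -0.78 with 7 risen and 14 fallen and an adjusted p of 0.144. The adjusted p was 0.378 after quantile normalization, 0.0592 with the top rows left out of the total, 0.0535 without P3 replicate 4 and 0.165 without the 4 libraries lowest in cardiomyocyte markers. Hmox1 (heme oxygenase) rose by 6.18 and Txnrd1 (thioredoxin reductase) by 3.56. Of 14 nuclear hormone receptors and early targets, Rara (2.02), Nr3c1 (1.84) and Per1 (1.09) rose and Klf15, a regulator of metabolism induced by glucocorticoids, fell by 2.33 on the log2 scale. That test also pointed down (camera adjusted p = 0.0189, and adjusted p = 0.788 with an estimated correlation) against a median of 0.36 and a mean of 0.31, with a scaled median of -0.89, 1 risen and 7 fallen and adjusted p of 0.0598. Scaling removed the calls of Nr3c1 (0.39) and Per1 (0.05) but not that of Rara (1.07). The list call was lost without adult replicate 1, 5, 6 or 7 (adjusted p between 0.0501 and 0.0869), with a 5 RPKM filter (0.104) and with a block by replicate number (0.0715). By fry, which tests a list against no change, the glycolysis, antioxidant and nuclear receptor lists all pointed up (adjusted p = 0.000107, 0.000629 and 0.0116).

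Of 14 growth factor and fetal growth genes, 12 rose and 1 fell (median 2.74, scaled 1.37, camera adjusted p = 0.279, after scaling 0.00483), led by H19. Of 13 fetal and neonatal contractile genes, 9 rose and 1 fell (median 3.72, scaled 2.40, camera adjusted p = 0.897), led by Tagln. Of 23 cardiac transcription factors, 10 rose and 1 fell (median 0.90, scaled -0.20, camera adjusted p = 0.511, pointing down), with Tbx20 rising by 2.48. After scaling, 1 of these factors rose and 5 fell. Of 19 extracellular matrix genes, 14 rose and 1 fell (median 3.37, scaled 1.98, camera adjusted p = 0.613, after scaling 0.0363), and Fn1, which encodes fibronectin, rose by 6.67. As deposited with an estimated correlation, the adjusted p was 0.842 for growth genes and 0.915 for matrix genes. Of 29 immediate early and dissociation stress genes, which can be induced while cells are isolated, 22 rose and 0 fell (mean 2.11, scaled median 0.71, camera adjusted p = 0.667), with Hmox1 leading. After scaling, 11 growth genes rose and 1 fell, 8 fetal contractile genes rose and 3 fell, 13 matrix genes rose and 4 fell, and 11 immediate early genes rose and 3 fell. In each of the 30 lists with a tested member, the counts adjusted over the list alone were those over all genes.

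All endothelial markers and some markers of other cell types also rose in neonatal libraries, though none of their lists was past the threshold. Over all genes 5496 of 9389 rose. Compared with this share, that of the endothelial markers was higher, that of the fibroblast markers near it and those of the smooth muscle and atrial markers lower. All 13 endothelial markers rose (median 2.91, scaled 1.49, camera adjusted p = 0.511, after scaling 0.0379, and adjusted p = 0.915 as deposited with an estimated correlation), including Eng (endoglin), which rose by 4.89 from 6.02 ± 6.74 RPKM in adults to 90.3 ± 35.2 at P1 and 262 ± 102 at P3. Of 8 fibroblast markers, 5 rose and 1 fell (median 2.20 and mean 1.77, with a test pointing down at camera adjusted p = 0.279; scaled 1.03), and Fbln2 (fibulin 2) rose by 4.16. Of 5 smooth muscle and pericyte markers, Mcam and Smtn rose by 4.93 and 1.72 (median 0.65 and mean 1.13, test pointing down at camera adjusted p = 0.461; scaled -0.90). Of 5 atrial and conduction markers, Nppa (atrial natriuretic peptide) and Myl4 (the atrial light chain of myosin) rose by 4.00 and 3.72 (median 0.65 and mean 1.58, test pointing down at camera adjusted p = 0.502; scaled -0.94). Both are also members of the fetal and neonatal contractile list. After scaling, 10 endothelial markers rose, 4 fibroblast markers rose and 2 fell, 1 smooth muscle marker rose and 2 fell, and 2 atrial markers rose and 2 fell. Smtn was then at 0.26, not called. The 1 Schwann, neuronal or adipocyte marker with a row, Erbb3, was not called, at -0.18. All 13 endothelial and 9 fibroblast markers averaged at least 1 RPKM in adult libraries as well.

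**Figure D3:**
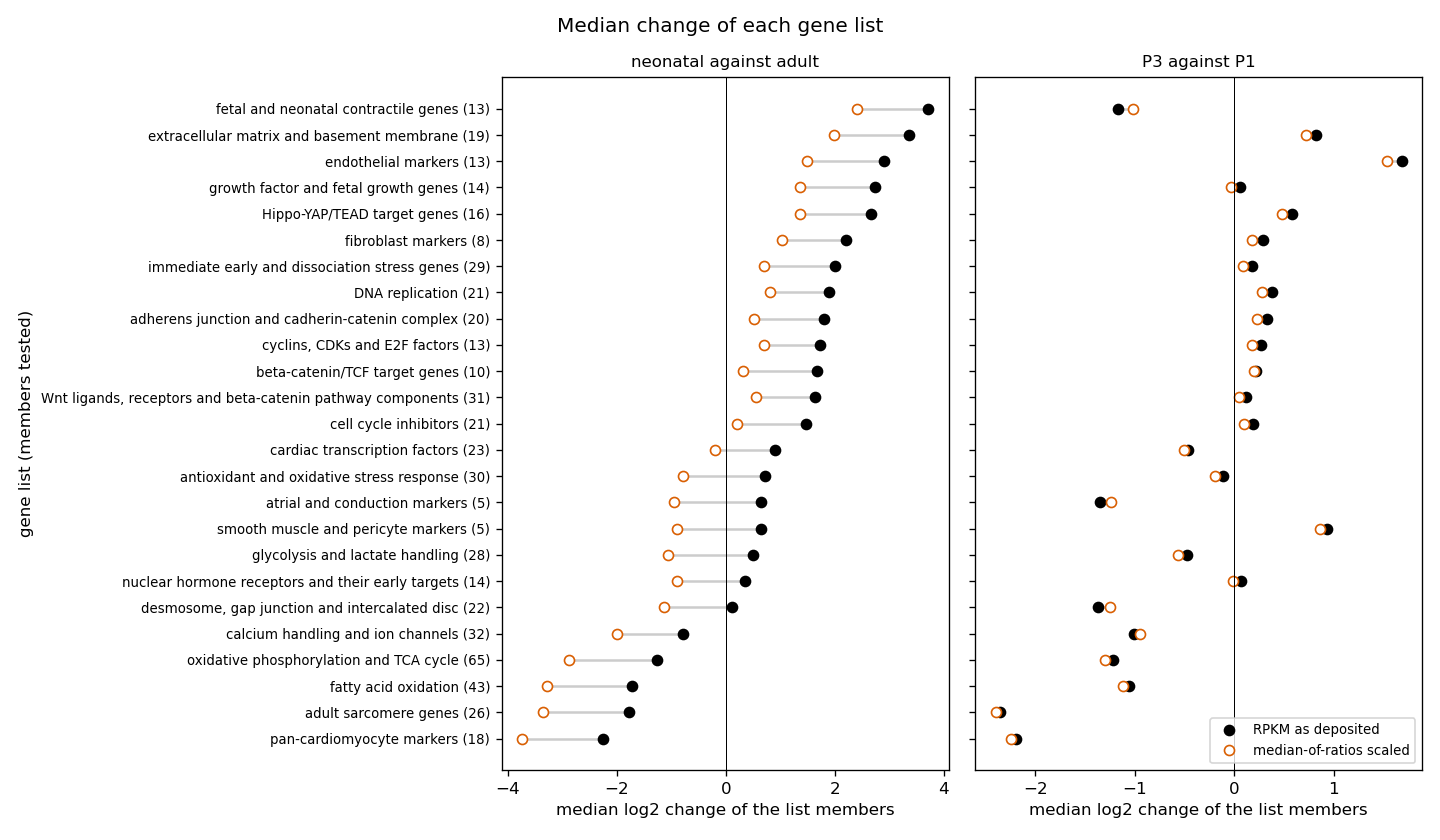
Median log2 change of the tested members of each gene list for neonatal against adult (left) and P3 against P1 (right) libraries; filled points are RPKM as deposited, open points are after median-of-ratios scaling, and the number of members is in brackets. For neonatal against adult, scaling shifts the lists down by about the median shift of all genes, with adult sarcomere genes at -1.78 and -3.35; for P3 against P1 the 2 readings lie close together.

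P1 and P3 libraries each differed from adults in largely the same genes, with a few cardiac genes moving apart. Nppa rose by 6.22 at P1 and 1.79 at P3 against adults, and Tbx20, a cardiac transcription factor, by 3.16 and 1.80. Scaling removed both calls at P3 (0.23 and 0.31). Tcap changed by -3.61 and -6.30 and Myoz2 by -2.06 and -4.77, so both stood farther below adults at P3 (limma adjusted p of the difference 0.0163 and 0.00648). Csrp3 (muscle LIM protein) and Actc1 (cardiac actin) were not called at P1, with 0.27 and -0.69, but fell at P3, with -3.87 and -4.67. After scaling both were called lower at P1 too (-1.31 and -2.27). In all, 5772 genes were called for P1 against adult (5403 higher, 369 lower; 93.6% higher) and 6335 for P3 against adult (5549 higher, 786 lower; 87.6% higher). After scaling the counts were 2993 (1261 higher, 1732 lower; 42.1% higher) and 4003 (1781 higher, 2222 lower; 44.5% higher).

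The calls of the P1 and P3 comparisons overlapped in 5014 higher and 351 lower genes, 5365 in all, and 2 genes were called in opposite directions; after scaling the overlap was 1144 higher and 1643 lower. Both comparisons use the same adult libraries, and 20 simulations of unchanged groups against shared controls gave 0 shared calls, but with at most 3 calls per direction in either simulated comparison that value sets no bound on the overlap of lists this long. Independent lists of these sizes would share 3193 higher and 30.9 lower genes. With the adult libraries divided into 4 odd and 3 even replicates, so that no library was shared, 5172 and 5297 genes overlapped. The log2 changes correlated across genes at r = 0.936 with a covariance of 1.62, against 0.402 and 0.0238 in the simulations; genes are not independent replicates.

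Between P3 and P1, cardiomyocyte lists were lower at P3 and endothelial markers higher. Nppb, which encodes the B-type natriuretic peptide (chromosome 4, 147985788 to 147987205), changed by -4.98 ± 0.78 (SE, limma adjusted p = 0.00390), from 1255 ± 994 RPKM at P1 to 53.0 ± 65.8 at P3 (SD, n = 4 each). Nppa, next to it (148000722 to 148002079), changed by -4.42 ± 0.72, Csrp3 (chromosome 7, 48830398 to 48848033) by -4.14 ± 0.59 and Actc1 (chromosome 2, 114047282 to 114053548) by -3.98 ± 0.51 (limma adjusted p = 0.00140). How reads shared by Actc1 and the skeletal form Acta1 were counted is not given in the sources used here. The largest rises were Apln, an apelin peptide made by tip cells of growing vessels (chromosome X, 48025146 to 48034853), by 2.29 ± 0.34 from 19.4 ± 8.48 to 96.4 ± 31.6 RPKM, and Prnd, a prion-like gene (chromosome 2, 131950861 to 131956130), by 2.19 ± 0.35. Cd93, an endothelial surface receptor (chromosome 2, 148436640 to 148443563), rose by 2.08 ± 0.46, and Robo4, an endothelial guidance receptor (chromosome 9, 37401897 to 37415115), by 2.05 ± 0.40 (limma adjusted p between 0.00386 and 0.0126 for these 4). Across all genes 614 were called, 149 higher and 465 lower at P3 (24.3% higher), and after scaling 554, 53 higher and 501 lower (9.57% higher). The balance depended on the fit: from only the libraries compared, 104 were higher and 89 lower (53.9% higher), and with a block by replicate number 129 and 151 (46.1% higher).

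This count depended on which libraries were included. Leaving out 1 library gave 984 (P1 replicate 1), 129 (P1 replicate 2), 172 (P1 replicate 3), 320 (P1 replicate 4), 1050 (P3 replicate 1), 259 (P3 replicate 2), 113 (P3 replicate 3) and 187 (P3 replicate 4). Without the 4 libraries lowest in cardiomyocyte markers, which leaves 3 P1 libraries and 1 P3 library, limma called 0 genes of 9216, with 489 at an unadjusted p under 0.05, and voom also called 0. Of 31 genes named for this comparison, 14 kept their call whichever library was left out: Actc1, Apln, Casq2, Csrp3, Fzd4, Hr, Nppa, Nppb, Nrap, Nt5e, Prnd, Robo4, Slc8a1 and Xirp2. The calls kept were 17, 18, 14 and 18 without P1 replicate 2, P1 replicate 3, P3 replicate 3 and P3 replicate 4, and 23 to 31 without any other neonatal library.

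Contractile, metabolic and intercalated disc lists were lower at P3. Of 26 adult sarcomere genes, 23 fell and 0 rose, or 25 adjusted over the list alone (median -2.35, scaled -2.40, camera adjusted p = 2.06e-20, and adjusted p = 0.269 with an estimated correlation). Of 18 pan-cardiomyocyte markers, 11 of which are also in the sarcomere list, 15 fell, or 17 adjusted over the list alone (median -2.19, scaled -2.25, camera adjusted p = 7.07e-15, and adjusted p = 0.269 with an estimated correlation). Of 65 oxidative phosphorylation and TCA cycle genes, 41 fell, or 54 adjusted over the list alone (median -1.21, scaled -1.30, camera adjusted p = 1.89e-25, and adjusted p = 0.413 with an estimated correlation). Cox6a2, a heart and muscle form of a cytochrome c oxidase subunit, changed by -2.13 and Cox7a1 by -1.85. Of 43 fatty acid oxidation genes, 18 fell and 1 rose, or 26 and 1 adjusted over the list alone (median -1.06, scaled -1.12, camera adjusted p = 5.97e-11, and adjusted p = 0.451 with an estimated correlation). The fatty acid carrier Fabp3 changed by -2.36 and the mitochondrial importer Cpt1b by -2.29. Of 32 calcium handling and ion channel genes, 15 fell, or 16 adjusted over the list alone (median -1.01, scaled -0.94, camera adjusted p = 4.25e-10, and adjusted p = 0.347 with an estimated correlation). Casq2 (calsequestrin) changed by -2.75 and the sodium-calcium exchanger Slc8a1 by -2.10.

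Of 22 desmosome, gap junction and intercalated disc genes, 12 fell, or 13 adjusted over the list alone (median -1.36, scaled -1.25, camera adjusted p = 9.93e-08, and adjusted p = 0.413 with an estimated correlation). Xirp2 and Nrap, actin-binding proteins of the disc and of growing myofibrils, changed by -3.22 and -2.94. Of 28 glycolysis genes, 8 fell (median -0.47, scaled -0.56, camera adjusted p = 0.000141, and adjusted p = 0.451 with an estimated correlation). The muscle form Pgam2 changed by -2.20 and Ldhb, the heart form of lactate dehydrogenase, by -2.12. Of 13 fetal and neonatal contractile genes, 7 fell, or 7 with 1 rise adjusted over the list alone (median -1.17, scaled -1.02, camera adjusted p = 0.00321, and adjusted p = 0.451 with an estimated correlation). Of 23 cardiac transcription factors, 6 fell and 1 rose, or 7 and 1 adjusted over the list alone (median -0.46, scaled -0.51, camera adjusted p = 0.00214, and adjusted p = 0.529 with an estimated correlation). Hopx changed by -2.04 and Nkx2-5 by -1.71. All 5 atrial and conduction markers fell (median -1.35, scaled -1.24, camera adjusted p = 7.96e-06, and adjusted p = 0.269 with an estimated correlation), and Myl4 changed by -2.50. The cardiomyocyte marker score dropped along with each of these lists, from 7.01 ± 0.657 at P1 to 4.78 ± 1.14 at P3, and the medians moved toward 0 without the 4 libraries lowest in these markers. That fit leaves 1 P3 library, assumed to vary like the other groups, and drops libraries by the markers themselves, so it cannot decide whether single members fell. The medians were then -0.91 for the sarcomere list, -0.92 for cardiomyocyte markers, -0.18 for oxidative phosphorylation, -0.22 for fatty acid oxidation, -0.43 for calcium handling and -0.62 for the disc. The others were -0.27 for glycolysis, -0.55 for fetal contractile genes, -0.13 for cardiac transcription factors and -0.63 for atrial markers. After scaling all libraries, 0 members rose and the numbers that fell were 24 sarcomere, 15 cardiomyocyte marker, 55 oxidative, 26 fatty acid, 13 calcium, 12 disc, 8 glycolysis, 7 fetal contractile, 4 cardiac transcription factor and 5 atrial genes. The fetal contractile call was also lost with limma arrayWeights (adjusted p = 0.0645) and by voom (0.481), which used only genes with recovered reads.

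Endothelial markers were higher at P3. Of 13, 2 rose over all genes, Robo4 and Ptprb (1.51, a phosphatase of endothelial cells), and 12 adjusted over the list alone (median 1.68, scaled 1.54, camera adjusted p = 1.97e-05, and adjusted p = 0.451 with an estimated correlation). Of 21 DNA replication genes, 0 were called (median 0.38, scaled 0.28, camera adjusted p = 0.0110, and adjusted p = 0.721 with an estimated correlation). Of 16 Hippo-YAP target genes, Crim1 rose by 1.32 and Nt5e changed by -2.06, or 1 rose and 2 fell adjusted over the list alone (median 0.58, scaled 0.48, camera adjusted p = 0.0371, and adjusted p = 0.644 with an estimated correlation). The DNA replication call was lost without P1 replicate 2 or 4 (adjusted p = 0.0744 and 0.0879), and the Hippo-YAP call without P1 replicate 1 or 3 or P3 replicate 2 or 3 (adjusted p = 0.113, 0.0602, 0.150 and 0.0745). Scaling removed the call of Ptprb (1.32, limma adjusted p = 0.0631), leaving 1 endothelial rise, and left the DNA replication and Hippo-YAP counts as they were. The Hippo-YAP call was also lost after rescaling to TPM (0.103), with the top rows left out of the total (0.0597), with a 5 RPKM filter (0.0842) and by voom (0.0744). By fry the lists of endothelial markers (0.0768), DNA replication (0.192) and Hippo-YAP targets (0.114) were not past the threshold, nor were cardiac transcription factors (0.177) and fatty acid, fetal contractile and glycolysis genes (0.0736 each). Without the 4 libraries lowest in cardiomyocyte markers the endothelial median was 1.29, and the Hippo-YAP adjusted p was 0.409.

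The remaining lists were not past the threshold between P3 and P1. Cyclins, CDKs and E2F factors had 0 of 13 called (median 0.27, scaled 0.18, camera adjusted p = 0.167), beta-catenin/TCF targets 0 of 10 (median 0.22, scaled 0.20; 0.752), immediate early genes 0 of 29 (median 0.18, scaled 0.09; 0.673) and fibroblast markers 0 of 8 (median 0.30 and mean 0.17 with a test pointing down, scaled 0.18; 0.880). The fibroblast values at P1 rest in part on replicate 1, with a score of 5.31 against 2.86 to 3.17 in the other P1 libraries. Growth factor and fetal growth genes had 0 of 14 called, or 1 risen adjusted over the list alone (median 0.06, scaled -0.03, camera adjusted p = 0.919). Among 20 adherens junction genes, Iqgap1 rose by 1.01 (0.90 after scaling, not called) while Arvcf, a catenin that binds cadherins, and the talin Tln2 fell, with changes of -1.31 and -1.25 (median 0.33, scaled 0.23, camera adjusted p = 0.846). Among 31 Wnt genes, the receptor Fzd4 rose by 1.40 and 1 gene fell, or 2 adjusted over the list alone (median 0.12, scaled 0.05, camera adjusted p = 0.323). Among 21 cell cycle inhibitors, 2 fell, Tob1 at -1.66 leading (median 0.19 and mean -0.01, scaled 0.09, test pointing up, camera adjusted p = 0.858). Gpx3, an extracellular glutathione peroxidase, was the antioxidant gene of 30 that fell, with -1.62 (median -0.11, scaled -0.19, camera adjusted p = 0.135), and Hr, a corepressor of nuclear receptors, the hormone receptor gene of 14 that fell, with -1.27 (median 0.07 and mean -0.09, scaled -0.01, test pointing down, camera adjusted p = 0.323). In the matrix list of 19, Fn1 rose by 1.33 and Itgb1bp2, a striated-muscle partner of integrin, changed by -1.75 (median 0.82, scaled 0.73, camera adjusted p = 0.0913, after scaling 0.0478, and adjusted p = 0.792 as deposited with an estimated correlation). Smtn, a smooth muscle protein, rose by 1.15 among 5 smooth muscle and pericyte markers (median 0.94, scaled 0.87, camera adjusted p = 0.0806). Other cadherins had 0 of 4 called, or 1 risen adjusted over the list alone, with a median of 0.28 (scaled 0.18). Among 4 mitosis genes, 3 histones and Erbb3, 0 were called (medians 0.03, -0.52 and -0.82, scaled -0.06, -0.58 and -0.62). After scaling, 1 inhibitor, 2 antioxidant and 2 adherens junction genes fell and 0 rose, and the other counts in this paragraph over all genes stayed the same.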

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

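The tests of explanations in this part were chosen only after the results were seen; the searches for libraries far from the others and for genes whose P1 and P3 changes differ were planned.

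Some libraries lay far from the others of their group by Dixon's test, 22 in 291 groups of values (68 genes and 29 list scores in 3 groups), where chance alone gives about 1 in 20. That number is not far above this share, and the groups are not independent, since genes and lists share the same libraries. Of these, 7 concerned P3 replicate 1, 6 P1 replicate 1, 6 adult replicate 4, 2 P3 replicate 4 and 1 adult replicate 7. In P3 replicate 1, the exchanger gene Slc8a1 stood at 11.6 RPKM (others 3.38 to 3.99) and Itgb1bp2 at 7.05 (1.16 to 1.39), while Mcam stood at 108 (172 to 181) and Prnd at 28.4 (59.5 to 67.7). The scores of that library were 3.01 for calcium handling (2.08 to 2.22), 5.59 for glycolysis (5.13 to 5.19) and 3.48 for cardiac transcription factors (2.89 to 2.97). In P1 replicate 1, the cadherin Fat1 stood at 15.9 RPKM (26.4 to 27.8) and the matrix gene Fbln2 at 128 (17.1 to 23.8). Its scores were 3.80 for desmosome and disc genes (4.79 to 4.99), 6.31 for adult sarcomere genes (7.45 to 7.68), 6.03 for cardiomyocyte markers (7.23 to 7.39) and 5.31 for fibroblast markers (2.86 to 3.17). In adult replicate 4, Cox7a1 stood at 2540 RPKM (695 to 1127), Cox6a2 at 2028 (863 to 1166) and Hopx at 106 (45.8 to 65.3), and the scores were 1.56 for DNA replication (0.97 to 1.22), 2.50 for mitosis (1.74 to 1.99) and 8.82 for oxidative phosphorylation (7.89 to 8.28). In P3 replicate 4 the scores were 4.33 for adherens junction genes (4.49 to 4.52) and 4.13 for immediate early genes (4.70 to 4.78), and in adult replicate 7 Myc stood at 3.09 RPKM (0.150 to 0.645).

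Among the genes named for the neonatal libraries, 9 differed between P1 and P3 in their change against adults, by limma's test of P3 minus P1. Those that stood farther below adults at P3 were Tcap (difference -2.70, adjusted p = 0.0163), Myoz2 (-2.71, 0.00648), Pln (-1.57, 0.0465), Dgat2 (-1.48, 0.0237) and Cox7a1 (-1.85, 0.0439). Tbx20 (-1.36, 0.0241) and Nppa (-4.42, 0.00390) were above adults at both ages and closer to them at P3. Iqgap1 (1.01, 0.0265) and Fn1 (1.33, 0.0175) stood farther above adults at P3.

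The 26 adult sarcomere genes and the other cardiomyocyte lists were lower at P3 than at P1, while 13 endothelial markers were higher. A single dilution factor per library is argued against, since the changes of 18 cardiomyocyte markers spread with an SD of 0.761, above that of each of the other 34 of 35 splits of the 8 libraries (highest other 0.692). A lower share of cardiomyocytes with all other cell types raised alike cannot be told apart from a change in the mix of those cells: the endothelial minus fibroblast score differed by 1.51 (exact permutation p = 0.0857), with the abundant endothelial genes Fabp4, Emcn and Pecam1 at 217, 57.8 and 43.2 RPKM at P1 and 764, 207 and 144 at P3, while of 8 fibroblast markers 0 were called (median 0.30), the most abundant being Dcn at 102 and 220 RPKM, Col3a1 at 116 and 73.8 and Fbln2 at 46.7 and 45.7. The small fibroblast change rests on P1 replicate 1, whose fibroblast score was 5.31. The other P1 libraries scored 2.86 to 3.17, below all P3 libraries (3.56 to 4.10). Fbln2 stood at 128 RPKM in P1 replicate 1 and at 17.1 to 23.8 in the other P1 libraries. Movement of the cardiomyocytes toward the adult state would have raised sarcomere genes, whose scaled median was -2.40 (exact permutation p = 0.0571), but that is left open too because the amount of other RNA is not known. A change inside the cardiomyocytes between P1 and P3 stays open as untested, and P1 replicate 1 was low in cardiomyocyte markers too, at 6.03.

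The median gene stood 1.25 higher on the log2 scale in neonatal than in adult libraries. After each library was rescaled to 1 sum of the RPKM of its rows, which removes reads outside them, the median was still 0.91. That rescaling also raised all values under the fixed pseudocount, so 0.91 cannot be set directly against 1.25. After the most abundant rows were also left out of the total the median was 0.57 (exact permutation p = 0.000155 for this and for 0.91, the smallest that 6435 arrangements can give). Measured by sums of RPKM, reads outside the rows and a few abundant rows thus do not make up the whole shift. They account for a part whose size was not estimated, since a sum of RPKM does not weigh rows by their reads. A difference in RNA content between neonatal and adult cells, as a biological explanation, was not tested.

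Cdh2 and Ctnnb1 were higher in neonatal libraries by 1.37 and 2.32 on the log2 scale as deposited. After median-of-ratios scaling the change of Cdh2 was -0.21 (exact permutation p = 0.392), so the shift of the whole table may account for its rise. For Ctnnb1 0.72 remained (exact permutation p = 0.000622), under the fold minimum, which argues against the shift as the whole cause. A change of that size was not rare, as the upper quartile of all genes was 0.695 after scaling. Cdh2 was lower where the cardiomyocyte score was low (r = 0.918 over the 8 neonatal libraries, centred within each age, exact permutation p = 0.00347). Neonatal libraries had the lower scores, so a lower cardiomyocyte share, if the score measures it, is argued against as the cause of its rise. Of the 18 markers in the score, 11 are also adult sarcomere genes. Between neonatal and adult libraries the score thus cannot tell the share of cardiomyocytes from their expression state. Ctnnb1 was higher where that score was low (r = -0.810, p = 0.0382), so RNA of other cells may account for part of its rise, by an amount that was not estimated. A rise of either RNA per neonatal cardiomyocyte stays open as a biological explanation, untested, because no value here measures the RNA content of a cell, and how either gene follows the score in adults was not tested.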

How the results depend on the processing

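The fits by voom and without the 4 libraries lowest in cardiomyocyte markers were chosen only after the results were seen; all other alternatives were planned. Scaling had the largest effect on the gene counts of the comparisons with adults, whereas the number of lists depended most on the list test. With median-of-ratios scaling and quantile normalization, the neonatal count was 3471 and 3486, the P1 count 2993 and 2894, the P3 count 4003 and 4069 and the overlap 2787 and 2690. With the top rows left out of the total the P1 count was 3693 and the overlap 3477. Cdh2 in neonatal libraries changed by 0.76 after rescaling to TPM, 0.48 with the top rows left out, 0.24 after quantile normalization and -0.21 after median-of-ratios scaling, where its direction turned, and Ctnnb1 by 0.72 under the last of these. By construction these scalings lower the typical neonatal gene against adults. For P3 against P1, 1308 genes were called with limma arrayWeights, 280 with a block by replicate number (the numbers are only shared labels), 401 by voom, 193 from only the libraries compared and 1159 with no fold minimum, which by construction calls more. The other causes were not tested. Without the 4 libraries, limma called 0 (489 at an unadjusted p under 0.05; voom 0), with the lone P3 library assumed to vary like the other groups, and Cox7a1 turned to 0.10. The number of lists past the threshold was 0 for both comparisons with an estimated correlation, and 25 (neonatal against adult) and 6 (P3 against P1) by fry, for causes that were not tested. By voom it was 8 for P3 against P1, on 7785 genes with recovered reads. There the sarcomere, cardiomyocyte marker and atrial lists had too few members to be tested, and the fetal contractile and Hippo-YAP calls were lost. Leaving out 1 library gave 5967 to 6164 genes for neonatal, 5646 to 5877 for P1 and 6227 to 6398 for P3 against adult, an overlap of 5238 to 5458, and 9 to 11 and 12 to 15 lists. For P3 against P1 it gave 984, 129, 172 and 320 without P1 replicates 1, 2, 3 and 4, and 1050, 259, 113 and 187 without P3 replicates 1, 2, 3 and 4. Cdh2 then ranged from 1.27 to 1.48 in neonatal libraries and from -0.92 to -0.53 between P3 and P1, and Ctnnb1 from 2.23 to 2.38 and from 0.54 to 0.68. For 37 genes named for the neonatal libraries besides Cdh2 and Ctnnb1, 1009 refits kept direction and call and 2 lost the call, both for Mad2l1, under median-of-ratios scaling and quantile normalization; 13 of the 37 have a voom value. For 31 genes named for P3 against P1, 742 kept it, 137 lost it and 1 turned. Depth limits genes near 1 RPKM, which rest on 18.9 to 44.3 reads at 2 kb.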

Other observations

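The gene groups and isoform pairs in this part, and their tests, were chosen only after the results were seen; the splits of the libraries were planned.

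All 82 cytosolic ribosomal protein genes rose in neonatal libraries (median log2 change 2.17, scaled 0.56 with 9 still called, camera adjusted p = 0.00531, after scaling 0.000787, and adjusted p = 0.733 with an estimated correlation), though how reads shared with their pseudogenes were counted is not given in the sources used here. Of 52 initiation factor genes, 44 rose and 1 fell (median 1.67, camera adjusted p = 0.0257, and adjusted p = 0.733 with an estimated correlation), but after scaling 8 rose and 4 fell, the median was 0.20 and the call was lost (adjusted p = 0.120). The 8 genes of the cytosolic chaperonin, which folds actin and tubulin, rose (median 2.33, scaled 0.73 with 0 called, camera adjusted p = 0.0507, after scaling 0.0314), as did all 5 minichromosome maintenance genes of the replication helicase (median 3.04, scaled 1.96 with 5 called, camera adjusted p = 0.0629, after scaling 0.00670). For both groups the adjusted p as deposited was 0.733 with an estimated correlation. Of 35 proteasome subunit genes, 32 rose as deposited (camera adjusted p = 0.0507), but the scaled median was -0.04 with 0 called (adjusted p = 0.872), and of 15 tubulin genes 12 rose and 2 fell (median 1.67, scaled 0.29 with 6 risen and 2 fallen, camera adjusted p = 0.516, after scaling 0.175). Genes that serve mitochondria went the other way relative to the rest: of 78 mitochondrial ribosomal protein genes 8 rose and 2 fell (median 0.23, scaled -1.30 with 55 lower, camera adjusted p = 1.17e-06, after scaling 2.78e-11, pointing down, and adjusted p = 0.733 with an estimated correlation). Of 33 carriers of the Slc25 family, 9 rose and 5 fell (median 0.28, scaled -0.83 with 2 risen and 15 fallen, camera adjusted p = 0.00703, after scaling 0.00724, pointing down, and adjusted p = 0.733 with an estimated correlation). From P1 to P3, 5 mitochondrial ribosomal protein genes fell and 0 rose (median -0.58, scaled -0.63 with 10 fallen, camera adjusted p = 2.15e-15, after scaling 1.38e-17, and adjusted p = 0.908 with an estimated correlation). The test of cytosolic ribosomal protein genes also pointed down at P3, with 0 of 82 called (median -0.21, camera adjusted p = 0.00921, after scaling 0.00902, and adjusted p = 0.908 with an estimated correlation). That of the minichromosome maintenance genes pointed up, with 0 of 5 called (median 0.61, camera adjusted p = 0.0323, after scaling 0.0262, and adjusted p = 0.908 with an estimated correlation). The other 5 groups were not past the threshold between P3 and P1 as deposited, the lowest camera adjusted p being 0.0738, but after scaling the proteasome genes were, pointing down (adjusted p = 0.0262, 0 called). Their adjusted p as deposited was 0.908 with an estimated correlation.

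Pairs of genes that code for a broadly expressed or neonatal form and an adult muscle form of the same protein were compared as ratios, which no scaling of the libraries can alter. The 12 pairs were picked around genes whose change had already been seen, so that their direction gives no further support. The neonatal minus adult log2 ratio was 11.23 for Rpl3 over Rpl3l, 8.23 for the glucose transporters Slc2a1 over Slc2a4, 7.87 for the elongation factors Eef1a1 over Eef1a2, 6.73 for the enolases Eno1 over Eno3 and 3.13 for the myosins Myh7 over Myh6. As a hypothesis, the ratios might move toward the adult value from P1 to P3. The test leaves this open: the mean distance from the adult ratio was larger at P3 by 1.30 (exact permutation of the libraries, p = 0.0571). In 1 pair, Myh7 over Myh6, P3 lay closer to the adult ratio and in 11 farther from it, but the pairs share the same libraries. Between P3 and P1, 0 pairs passed the threshold (exact permutation, lowest adjusted p = 0.137). With 70 arrangements the smallest p of a pair is 0.0286, so a pair could pass only if most of the 12 reached that value. Broad forms are also made by other cell types, whose markers differed between P1 and P3 and between neonatal and adult libraries. The neonatal against adult ratios may thus in part reflect the mix of cells, which was not tested. Rpl3l averaged only 0.920 RPKM at P1 and 0.408 at P3.

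Chance was tested by dividing the same libraries in other ways. For the counts of genes against adults, 1 of 100 splits, the real one, gave as many: 6071 for neonatal libraries (highest other 3552), 5772 for P1 (highest other 3725) and 6335 for P3 (highest other 4180). This argues against chance in how these libraries were divided. Chance between animals or preparations was not tested, as the labels do not say whether the libraries of a group came from separate animals. For the 5365 calls shared by P1 and P3, 1 of 100 splits, the real one, gave as many (highest other 0), but all 99 others called 0 genes in at least 1 of the comparisons, so that this adds nothing to the counts above. Chance cannot be excluded for P3 against P1, where 2 of 35 splits gave at least the real 614 genes; the other, with 906, set P1 replicate 1 and P3 replicates 2, 3 and 4, the libraries lowest in cardiomyocyte markers, against the rest. Nor can it be excluded for the number of lists, where 40 of 100 splits gave at least the 11 of neonatal against adult (highest other 16) and 13 of 35 at least the 13 of P3 against P1 (highest other 16).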
